A study of Mus musculus with 9 samples.

How the data were processed

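RNA of mouse B lineage cells was measured on Affymetrix Mouse Genome arrays, a 1-colour platform that reads each transcript with a set of short probes. The 9 arrays form 3 groups of 3: sorted pre-B cells of wild-type mice, leukaemia cells from lymph nodes of p53 and Prkdc double-mutant mice, and cultured pro-B cells of wild-type mice. Groups and replicate numbers came from the sample titles. Per the labels, the wild-type mice were C57B/6 and the leukaemic mice a mix of 129/Sv and BALB/C, and leukaemia samples held at least 85% CD19-positive cells. Nothing in the labels says whether replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. For the leukaemias, medians of 2.7, 2.16 and 0.1 over a block of 15 neighbouring genes, described below, argue against 3 repeat measurements of 1 sample. Whether they came from separate animals stays unknown.

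The values deposited by the authors were MAS5 signal intensity per probe set on a linear scale, with GCOS and MAS5 named in the submitters' processing notes and versions not given in the sources used here. In the deposited intensity values, the mean after trimming 2% at each end was 150 on every array, so each array had been scaled to a common target. Such scaling sets aside any difference in total RNA between groups. The table used held no detection calls, so low signals were not separated from background and a fold against a dim group depends on the offset. The number of arrays limits the precision of every value.

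Probe sets were named through the platform annotation, and symbols were checked by gene identifier against RefSeq genes of the GRCm38.p6 assembly. Of 45101 probe sets, 64 were controls. Of the other 45037, 34945 had 1 gene symbol, 932 had several and 9160 were not named in that annotation. The gene identifier of 34741 was found in the RefSeq list, and 0 symbols were replaced. The files name no genome build, so positions are not printed and the assembly served only for names and gene order. Probe sets with several symbols or without a name were left out. For that reason Trp53, Cd19 and Lyn are not analysed here.

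Signals were transformed to log2(signal + 7.22), the offset being the 20th percentile of the table, and no further normalization was applied. Log2 fold changes are on this scale and understate the change of dim genes. Each of 18193 genes was read by its probe set with the highest mean. The 12430 genes with a mean above the 40th percentile of the table (a log2 value of 4.93) were tested, and 5763 were below it. A linear model with 3 group means was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 6 residual and 4.27 prior degrees of freedom). P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene counted as changed at an adjusted p under 0.05. Every adjusted p of a gene is from this limma test, two-sided.

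Genes were named by a rule written before the data were examined. It took the 8 highest and 8 lowest log2 fold changes of each comparison among changed genes at least 2-fold apart whose arrays did not overlap. It also took the 8 strongest changes in each direction shared by both leukaemia comparisons, up to 4 changed members of each fixed list, and a fixed set of B cell genes. Genes named outside the rule are said to be so. Probe sets whose names end in x or s can read related transcripts, which is stated where it applies.

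The 27 gene lists were also written before the data were examined. They cover B cell receptor signalling, lineage factors, proliferation, metabolism, stress pathways and markers of other cell types. Each list was compared with all other tested genes by limma's camera with a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the 81 tests of 27 lists in 3 comparisons. Camera was repeated with a correlation estimated from the residuals, and fry tested whether a list's genes moved on balance in 1 direction. Members were also counted with the adjustment over the list alone.

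The same code was tested on simulated data in which 200 of 12430 genes were changed. In the simulation of leukaemia against pre-B cells it recovered 36% of 2-fold and 94% of 4-fold changes with 5 false calls, against pro-B cells 46% and 94% with 5, and for pro-B against pre-B cells 34% and 96% with 4. For leukaemia against pre-B cells, 9 of 9 shifted lists were recovered and 0 unshifted lists were called. Genes were simulated independently of each other, so this does not check list calls whose members are correlated. In the measured data the estimated correlation reached 0.642, for natural killer cell markers. The overlap of both leukaemia comparisons was set beside 100 simulations of unchanged groups, since these comparisons share arrays.

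By choices made in advance, the analysis was repeated with another offset and with changes of the normalization, the filter, the variance model, the minimum fold, the choice of probe set, the replicate number as a block, the groups in the fit and the set test, and without each array in turn. Hybridization controls are bacterial and phage transcripts added for hybridization, and they are not read here as a standard of RNA amount. Scaling each array to its hybridization controls was added after the data were seen. So were list tests without Pigq, which entered the glycolysis list through the older symbol Gpi1, and without Myc in the list of its own targets.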

Results

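Expression was compared between B cell leukaemias arising in mice without p53 and with the scid form of Prkdc, a kinase needed to join broken DNA ends, and normal B cell precursors. The series concerns inhibition of the kinase SYK as a treatment of precursor B cell leukaemia, so the comparisons ask how the leukaemias differ from normal precursors and where Syk and its pathway stand. Each group had 3 arrays. Sorted pre-B cells and cultured pro-B cells were wild type. Because the leukaemias differ from both in strain as well as genotype, and the normal groups differ from each other in culture as well as stage, these cannot be separated. The leukaemias also came from lymph nodes. Signals of granulocyte genes, H2-Ea and Xist, given below, differed between the normal groups too, so stage and culture need not be their only differences. The median signal of the arrays lay between 29.8 and 41.4. Arrays of a group correlated at r = 0.973 to 0.974 over genes in pre-B cells, 0.95 to 0.953 in leukaemias and 0.942 to 0.981 in pro-B cells, where replicate 3 stood apart with a mean r of 0.943. The first principal component held 38.5% of the variance and the second 36.6%.

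Of the targeted genes, Prkdc was read by a single probe set and Trp53 was not analysed here. Prkdc signals were 76.6, 46.1 and 46.9 in pre-B cells, 100, 71.5 and 103 in leukaemias, and 48.8, 38.7 and 25.5 in pro-B cells. The scid allele is a point mutation, and whether the probe set covers it is not known from the files, so these signals do not check the genotype. Prkdc was higher in leukaemias than in pro-B cells by 1.16 ± 0.27 on the log2 scale (SE, adjusted p = 0.0099; 0.13 when arrays were scaled to hybridization controls, and 0.0058 to 0.13 over all settings). Against pre-B cells the difference of 0.65 ± 0.27 did not pass (adjusted p = 0.089), although it did with quantile normalization (0.03) and without pre-B replicate 1 (0.047), the range over all settings being 0.03 to 0.48.

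Syk, the kinase that relays signals from the B cell and pre-B cell receptors, was abundant in all 3 groups and highest in sorted pre-B cells. Its signal was 6240 ± 682 in pre-B cells, 2530 ± 743 in leukaemias and 2570 ± 36.5 in pro-B cells (mean ± SD, n = 3). Syk fell by 1.33 on the log2 scale from pre-B cells to leukaemias (SE 0.22, adjusted p = 0.0012) and by 1.27 from pre-B to pro-B cells (SE 0.22, adjusted p = 0.0019). Leukaemias and pro-B cells differed by -0.06 ± 0.22 (adjusted p = 0.87), a difference that changed sign to 0.28 with the mean of all probe sets, to 0.02 without leukaemia replicate 1 and to 0.09 without leukaemia replicate 3. Of the 4 Syk probe sets, 3 went down from pre-B cells to leukaemias and the fourth stood at 0.01. Between leukaemias and pro-B cells the other 3 probe sets stood at 0.23, 0.08 and 0.89, against -0.06 for the probe set used. The pre-B arrays also had high signals of granulocyte genes, given below, and whether such cells added to their Syk signal was not tested.

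Genes of the receptor complex itself split. Cd79a and Cd79b, which encode the signalling chains of the receptor, stayed high, with signals of 6060 ± 685 and 7460 ± 2240 in leukaemias against 7810 ± 776 and 10000 ± 394 in pre-B cells. Their differences of -0.37 ± 0.18 and -0.48 ± 0.25 did not pass (adjusted p = 0.14 and 0.18), but both passed with quantile normalization (0.0093 and 0.0073) and with scaling to hybridization controls (0.023 and 0.019). Over all settings their adjusted p ranged from 0.0093 to 0.35 and from 0.0073 to 0.52. Vpreb1 and Igll1, which form the surrogate light chain, had their lowest signals in the leukaemias with the probe sets used. Vpreb1 signals were 20.1 ± 28.5 in leukaemias, 804 ± 342 in pre-B cells and 9730 ± 2330 in pro-B cells, and Igll1 signals were 54.6 ± 29.2, 913 ± 234 and 10000 ± 2640. The Igll1 probe set can read related transcripts, and a second, dim Igll1 probe set gave changes of the opposite sign. Of the adaptor Blnk and the kinase Btk, which act downstream of SYK, Blnk fell by 0.91 against pro-B cells (SE 0.21, adjusted p = 0.011). Against pre-B cells Blnk differed by -0.42 (adjusted p = 0.16; 0.047 without leukaemia replicate 2, 0.015 with quantile normalization and 0.021 with hybridization controls; range 0.015 to 0.39), and Btk by -0.15 (adjusted p = 0.56).

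**Figure D1:**
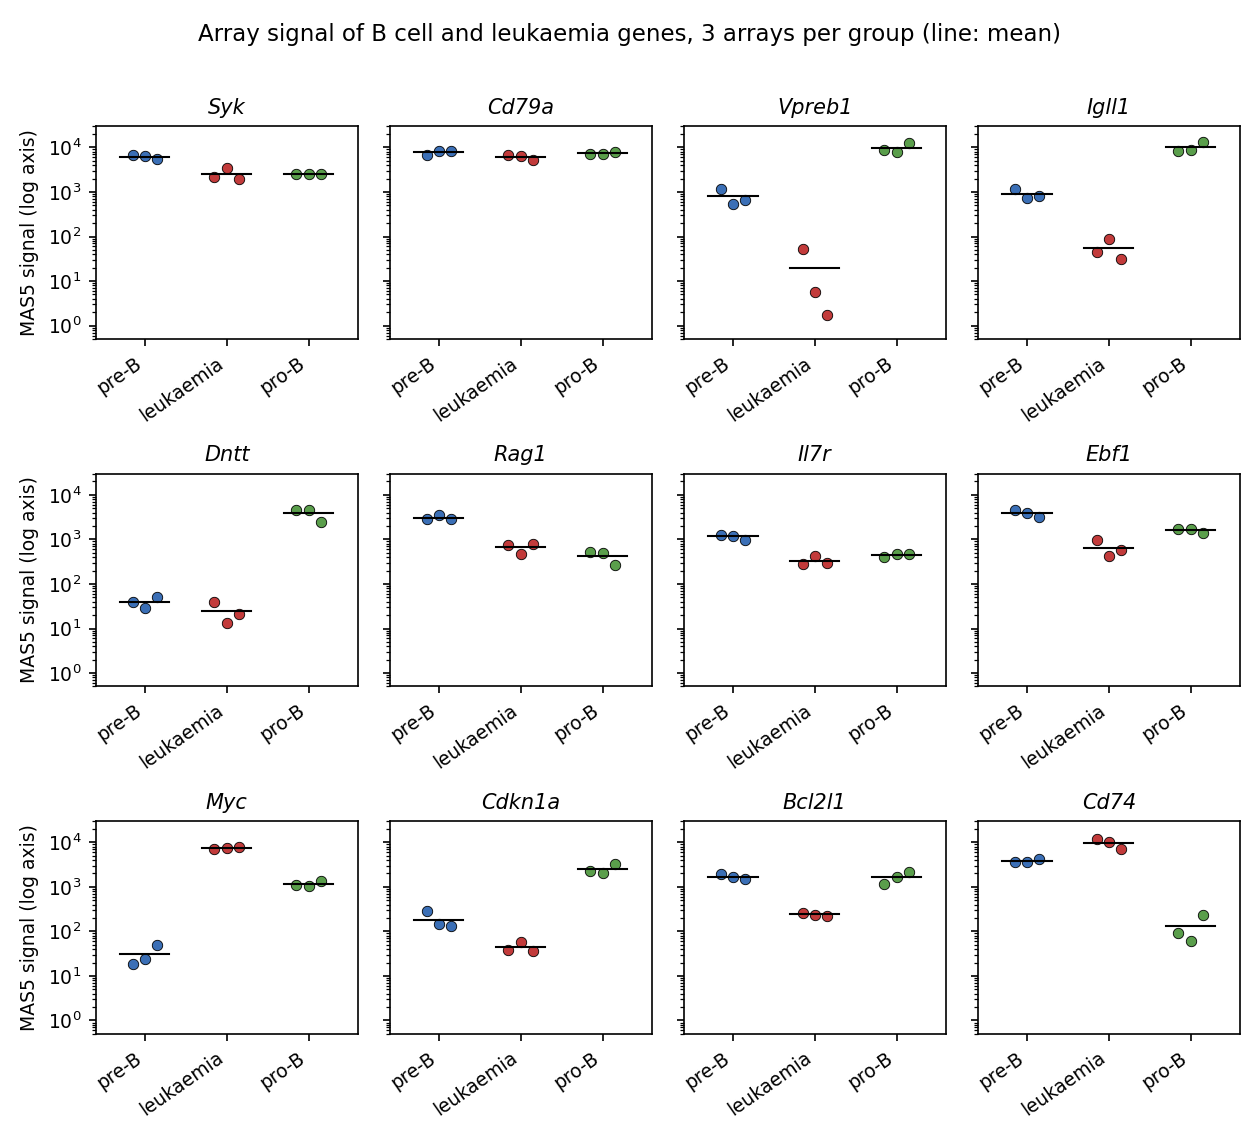
MAS5 signal on a log axis (vertical) of 12 B cell and leukaemia genes in sorted pre-B cells, leukaemias and cultured pro-B cells (horizontal). Each point is an array and each line the mean of 3 arrays. Myc signals were 7260, 7440 and 7740 in the leukaemias, above every array of the other groups, and Vpreb1 and Igll1 signals were lowest there.

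Against sorted pre-B cells, the leukaemias carried much more RNA of Myc, a transcription factor that promotes growth and ribosome production. Its signal rose from 30.9 ± 17 to 7480 ± 243 (n = 3), a log2 change of 7.71 ± 0.28 (SE, adjusted p = 6.3e-07). All 22 tested members of the list of MYC targets and ribosome biogenesis, of which Myc itself is a member in each comparison, rose, among them the spermidine synthase Srm (4.66), the nucleolar protein Rrp9 (4.47) and the RNA polymerase I subunit Polr1b (3.48). The transcription factors that set B cell identity fell, 12 of 17 members against 1 that rose, led by Ebf1 (-2.63 ± 0.28), Erg (-2.17), Foxo1 (-1.93) and Irf4 (-1.87). The Foxo1 probe set can read related transcripts and 3 of the 4 Foxo1 probe sets went down. In total 4092 of 12430 genes changed, 1964 higher and 2128 lower, and 1197 and 1279 of these were at least 2-fold apart. The arrays of both groups did not overlap in 6062 genes (48.8%), where chance gives 10%.

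MYC targets passed camera (adjusted p = 1.3e-18) and passed with the estimated correlation (0.046). Without Myc itself the list passed at 2.6e-17 and at 0.049 with the estimated correlation. The B lineage factors passed at 0.00023, with adjusted p = 0.083 with an estimated correlation. Targets of FOXO factors, which act when growth signals are low, fell in 9 of 13 tested members, including the cyclin Ccng2 (-2.79), the cell cycle inhibitor Cdkn1b (-2.28) and the recombinase Rag1 (-2.21 ± 0.29), while 0 rose. That list passed at 8.9e-05, with adjusted p = 0.083 with an estimated correlation. Il7r, the receptor of the growth factor IL-7, and Bcl6, a transcriptional repressor, belong to the same list and fell by 1.79 (adjusted p = 0.0002) and by 1.72 (adjusted p = 0.0006). Immediate early genes fell in 9 of 16 members (10 adjusted over the list alone), with Egr1 at -2.58 and Zfp36 at -1.82, and passed at 0.0039 (adjusted p = 0.41 with an estimated correlation). Of plasma cell markers 4 of 6 fell, with Sdc1 at -2.78 and Xbp1 at -1.51, both read by probe sets that can read related transcripts. That list passed at 0.0044 (adjusted p = 0.16 with an estimated correlation).

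Of the 14 tested members of the glycolysis list 7 rose (8 adjusted over the list alone) and 2 fell, with lactate dehydrogenase Ldha at 2.56 ± 0.22 and Pkm at 1.68 (adjusted p = 0.012, and adjusted p = 0.46 with an estimated correlation). The list held Pigq, a gene of another pathway matched through an older symbol it shares with a glycolytic enzyme, and without it 7 of 13 rose and 2 fell (adjusted p = 0.01, and adjusted p = 0.45 with an estimated correlation). Pdk1, a kinase that restrains pyruvate oxidation, rose from 19.3 ± 4.32 to 899 ± 154. Targets of the stress factor ATF4 rose in 6 of 11 members and fell in 1, with asparagine synthetase Asns at 3.25 and Phgdh of serine synthesis at 2.89 (adjusted p = 0.01, and adjusted p = 0.43 with an estimated correlation). The Phgdh probe set can read related transcripts. Cholesterol synthesis genes rose in 5 of 15 members, with Sqle at 2.51 and Cyp51 at 2.09 (adjusted p = 0.034, and adjusted p = 0.18 with an estimated correlation), although the list median of 0.32 became -0.04 with scaling to hybridization controls and the call was lost without pre-B replicate 2 (0.053), with the stricter filter (0.054) and with the mean of probe sets (0.053; range over settings 8.4e-05 to 0.18).

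In the pre-B cell receptor complex 3 of 6 fell, including Vpreb1 (-5.33 ± 0.6, adjusted p = 0.00014) and Igll1 (-3.97 ± 0.34, adjusted p = 3.2e-05). The list passed at 0.035 (adjusted p = 0.43 with an estimated correlation), but not without leukaemia replicate 3 (0.053), with the stricter filter (0.062) or without probe sets that can read related transcripts (0.22; range over settings 0.00096 to 0.43). Receptor-proximal signalling genes fell in 6 of 14 members, among them the adaptor Pik3ap1 (-3.38), the kinase Blk (-1.34) and Syk, and 1, the scaffold Bank1, rose by 1.51. This list passed at 0.048 (adjusted p = 0.2 with an estimated correlation) and did not pass without pre-B replicate 3 (0.058), leukaemia replicate 1 (0.072) or pro-B replicate 1 (0.061), 2 (0.06) or 3 (0.055), nor with the replicate block (0.053; range over settings 0.0002 to 0.2).

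Some genes of other cells moved with this comparison. Granule and alarm proteins of granulocytes were high in the pre-B arrays and fell in the leukaemias: Camp (-5.61), Lcn2 (-4.9), Hp (-4.88) and S100a9 (-4.62), the last from a signal of 11100 ± 1110 to 498 ± 314. Outside the rule, 10 other granulocyte genes were read in a fit without the low-signal filter. Of these, 7 were higher in pre-B cells than in both other groups, and 0 were higher in leukaemias than in both normal groups. Their median was -1.99 in leukaemias and -2.14 in pro-B cells, each against pre-B cells. Granulocyte RNA in the pre-B arrays may therefore enter falls against pre-B cells in either comparison, which was not tested. Of the myeloid list as a whole 3 rose and 6 fell among 19 members (5 and 7 adjusted over the list alone; adjusted p = 0.4). The highest of those that rose, named here outside the rule, was the macrophage gene C1qb (2.52, adjusted p = 0.00028), with signals of 348, 593 and 202 in leukaemias and 52.5, 52.5 and 59 in pre-B cells from a probe set that can read related transcripts. Of 5 erythroid genes 4 fell, including Klf1 (-3.07) and Slc4a1 (-2.13), and the list passed at 0.012 (adjusted p = 0.17 with an estimated correlation) but not without an offset (0.22) or with the stricter filter (0.071; range over settings 0.00061 to 0.22). Genes of salivary secretions were among the 8 strongest to rise, with Dcpp1 at 6.11, Bpifa2 at 6.02, Scgb2b27 at 5.73 and Smr3a at 5.03, the last read by a probe set that can read related transcripts. H2-Ea, a chain of MHC class II, fell by 6.91 from 3310 ± 86.1 to 21.4 ± 10.1. Xist, the RNA that silences an X chromosome in female cells, gave signals of 2880, 5560 and 5870 in pre-B cells and 43.6, 49.4 and 119 in leukaemias, and the H2-Ea and Xist probe sets can read related transcripts.

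Other named genes included the LIM domain protein Lmo7 (5.6), the adhesion molecule Hepacam2 (5.26), the metalloreductase Steap4 (-5.51) and the receptor kinase Epha2 (-4.76), and the Hepacam2 probe set can read related transcripts. Dntt, which adds bases at recombined ends, was low in both groups and differed by -0.63 (adjusted p = 0.2). The other 16 of the 27 lists did not pass, with adjusted p from 0.059 for DNA replication to 0.86 for the BCL2 family. Members of the latter moved both ways, so that its median was -0.17 and its mean 0: the death agonist Bid rose by 3.6 and the survival gene Bcl2l1 fell by 2.77. Among 16 p53 targets 3 rose and 4 fell (adjusted p = 0.5), with the cell cycle inhibitor Cdkn1a at -1.84. Changes are relative to the scaling of the arrays: with hybridization controls as the standard, the median gene shifted by -0.39 and the split became 1010 higher and 3304 lower, whereas it was 2108 and 1706 with each array's median as the standard and 2226 and 1978 with quantile normalization.

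**Figure D2:**
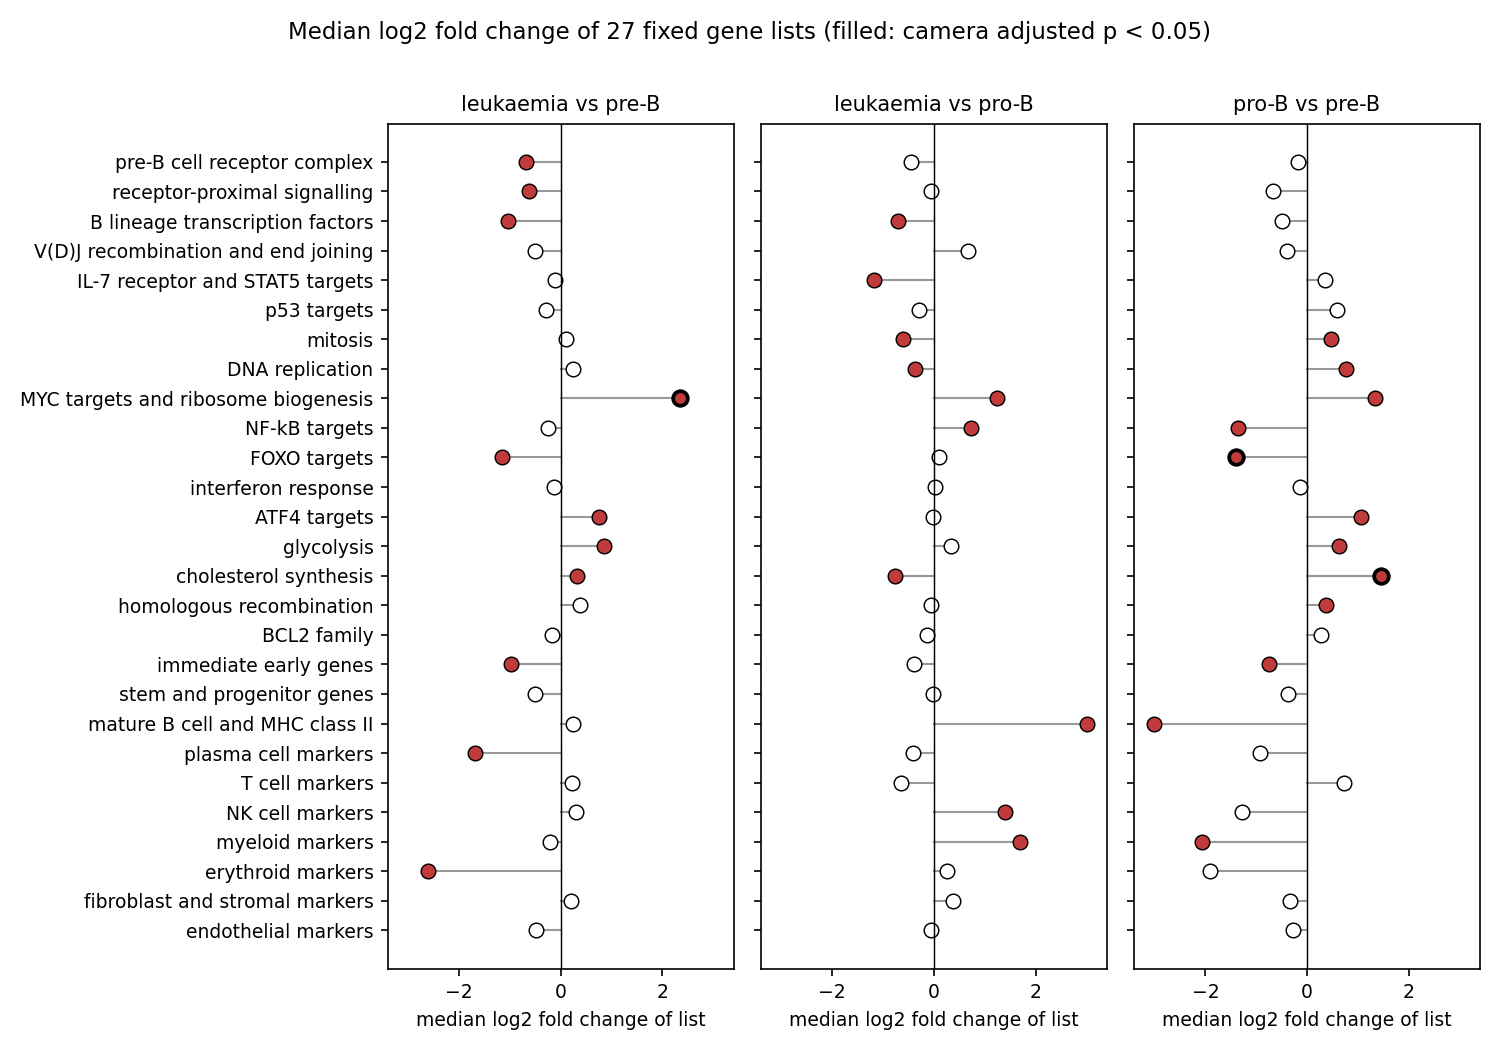
Median log2 fold change (horizontal) of 27 fixed gene lists (vertical) in each comparison. Filled points passed camera with the preset correlation and a thick outline marks those that also passed with the estimated correlation. MYC targets had medians of 2.34, 1.24 and 1.33, and mature B cell and MHC class II genes 0.23, 3.02 and -3.01.

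Against cultured pro-B cells, the leukaemias carried more RNA of most genes in the list of mature B cell and MHC class II genes. The invariant chain Cd74 rose from 130 ± 94.5 to 9820 ± 2380 (log2 change 6.35 ± 0.4, adjusted p = 3.6e-06, n = 3), followed by the class II chains H2-Aa (5.61) and H2-Eb1 (4.8) and the surface antigen Ms4a1 (5.24). In that list 13 of 16 rose. Among the named genes that fell were Vpreb1 (-8.97), Igll1 (-7.41), Dntt (-6.95, from 3870 ± 1240 to 24.7 ± 13.7) and the lineage factors Erg (-5.76) and Lef1 (-2.8), whereas the list of stem and progenitor genes did not pass (0 rose and 3 fell of 11, adjusted p = 0.35). Myc was higher by 2.69 ± 0.28 (adjusted p = 8.2e-05). In total 3153 genes changed, 1542 higher and 1611 lower, 939 and 949 of them at least 2-fold, and the arrays did not overlap in 4768 genes (38.4%, chance 10%).

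The list of mature B cell and MHC class II genes passed camera at 1.5e-09 (adjusted p = 0.17 with an estimated correlation). Adjusted over the list alone, 13 of its members were up and 1 down. MYC targets rose in 17 of 22 members (20 adjusted over the list alone), with the nucleolar proteins Npm1 at 2.46 and Ncl at 2.38, at 1.3e-09 (adjusted p = 0.088 with an estimated correlation). B lineage transcription factors fell in 8 of 17 and rose in 1, at 0.0027 (adjusted p = 0.13 with an estimated correlation), with Ebf1 at -1.34 and Irf8 at -1.28. Targets of the IL-7 receptor and STAT5 fell in 7 of 12 and rose in 3, at 0.0026 (adjusted p = 0.16 with an estimated correlation). They included the feedback inhibitors Socs2 (-4.14) and Cish (-3.38) and the cyclin Ccnd3 (-2.96), whereas Il7r itself differed by -0.43 (adjusted p = 0.18; 0.013 with hybridization controls and up to 0.4 in other settings). Targets of NF-kB rose in 6 of 14 (7 adjusted over the list alone) and fell in 1, with Cd40 at 3.79 and Birc3 at 2.26, at 0.0045 (adjusted p = 0.43 with an estimated correlation).

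Mitosis genes fell in 11 of 21 and rose in 3 (12 and 4 adjusted over the list alone), with the kinases Aurka at -1.56 and Cdk1 at -1.23 among those that fell and the motor protein Cenpe at 1.54 among those that rose, at 0.027 (adjusted p = 0.42 with an estimated correlation), and the call was lost without leukaemia replicate 2 (0.097), with the stricter filter (0.059) and with the mean of probe sets (0.058; range over settings 0.0025 to 0.42). DNA replication genes fell in 5 of 23 and rose in 1, with the thymidine kinase Tk1 at -1.35, at 0.013 (adjusted p = 0.43 with an estimated correlation). Cholesterol synthesis genes fell in 7 of 15 (9 adjusted over the list alone), with Msmo1 at -2.08 and Dhcr7 at -1.1, at 0.0004 (adjusted p = 0.083 with an estimated correlation). The p53 list did not pass (5 fell and 1 rose of 16, adjusted p = 0.082), although Cdkn1a fell by 5.62 from 2540 ± 600 to 44.5 ± 12.8. In the BCL2 family, 3 rose and 3 fell of 13 (adjusted p = 0.44), with Bcl2l1 at -2.69 and Bid at 1.6.

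Of the marker lists of other cells, those of myeloid and natural killer cells passed against pro-B cells. Myeloid markers rose in 15 of 19 (16 adjusted over the list alone), with the complement gene C1qb at 3.71, Mpeg1 at 3.21 and Cybb at 3.04, at 1.9e-09 (adjusted p = 0.17 with an estimated correlation). The C1qb probe set can read related transcripts, as can those of H2-Aa and Igll1. Natural killer cell markers rose in 3 of 6 (4 adjusted over the list alone), with Nkg7 at 1.64, at 0.035 (adjusted p = 0.46 with an estimated correlation), a call lost without leukaemia replicate 1 (0.09) or pro-B replicate 3 (0.076), by fry (0.057), with the stricter filter (0.24) and with the mean of probe sets (0.073; range over settings 0.0039 to 0.46). T cell markers went both ways, with 1 up and 2 down of 6 (1 and 3 adjusted over the list alone; adjusted p = 0.27), Lat at -6.22, Thy1 at -2.86 and Cd2 at 4.65. Of erythroid markers 0 rose and 2 fell of 5 (1 and 2 adjusted over the list alone; adjusted p = 0.61), with a median of 0.25 and a mean of -1.11, and of endothelial markers 1 rose and 1 fell of 8 (adjusted p = 0.8). The salivary genes Bpifa2 (6.47), Scgb2b27 (5.89) and Dcpp1 (5.62) were again among the strongest.

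Further named genes were Iglv1, a light chain variable segment that can share sequence with related segments (7.88), the extracellular protein Reln (7.1) and the carboxypeptidase Cpn1 (5.8) among those that rose. Among those that fell were the myosin light chain Myl10 (-8.19), the growth factor Tgfb3 (-6.98), the carbonic anhydrase Car2 (-6.58), the peptidase Enpep (-6.46) and the transcription factor Foxc1 (-6.45). Differences of Cd79a (-0.29, adjusted p = 0.27), Cd79b (0.18, 0.64), Btk (0.37, 0.16), Bcl6 (-0.2, 0.61) and Rag1 (0.67, 0.12) did not pass, although Cd79a did with quantile normalization (0.039) and with hybridization controls (0.013; range 0.013 to 0.52). Those of Cd79b, Btk and Bcl6 also changed sign under some settings. The 17 lists not called had adjusted p from 0.064 to 0.86. With each array's median as the standard the split of changed genes was 1114 higher and 1829 lower, and with hybridization controls it was 527 and 3845, with the median gene shifted by -0.47.

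Between the leukaemias and both normal groups, 748 genes were higher and 828 lower in the same direction in both comparisons, 1576 in total. Besides the salivary genes, Lmo7 (5.6 over pre-B and 5.54 over pro-B cells), Hepacam2 (5.26 and 5.53), the pseudokinase Trib1 (4.22 and 4.42) and the chitinase Chia1 (4.16 and 4.79) were the highest in both. The lowest in both were Vpreb1, Igll1, Car2 (-4.64 and -6.58), the adhesion receptor Adgrg1 (-4.36 and -6.07), Gfra1 (-4.06 and -3.46), Tusc1 (-4.06 and -3.62), the glycosyltransferase B3gnt8 (-3.47 and -4.27) and Rsph9 (-3.46 and -3.69). Trib1 varied between leukaemias, with signals of 146, 1470 and 358. Independent lists of these sizes would share 244 higher and 276 lower genes, and simulated unchanged groups shared 0, a value that the adjustment for many tests itself holds low. Without adjustment, 2392 genes had p under 0.05 in both with the same sign, against 140 in simulated unchanged groups, and 67.7% of all genes had the same sign, against 66.7%. Part of the excess may come from the leukaemia arrays that both comparisons share. Opposite directions were found for 154 genes, 2362 were called only against pre-B cells and 1423 only against pro-B cells.

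Pro-B cells in culture and sorted pre-B cells differed in B cell, metabolic and myeloid genes. Dntt rose from 40 ± 10.5 in pre-B to 3870 ± 1240 in pro-B cells (log2 change 6.32 ± 0.35, adjusted p = 2.7e-06, n = 3), with Igll1 (3.44), Vpreb1 (3.64) and Erg (3.59). Mature B cell and MHC class II genes fell in 15 of 16 and 1 rose, with Ms4a1 at -5.71 and Cd74 at -4.99. Myc rose by 5.02 ± 0.28 (adjusted p = 2.7e-06). In total 3818 genes changed, 1928 higher and 1890 lower in pro-B cells, 1048 and 1212 of them at least 2-fold, and the arrays did not overlap in 6078 genes (48.9%, chance 10%).

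The list of mature B cell and MHC class II genes passed at 1.2e-10 (adjusted p = 0.16 with an estimated correlation). MYC targets rose in 17 of 22, with Rrp9 at 3.67 and Srm at 3.41, at 5.5e-10 (adjusted p = 0.088 with an estimated correlation). Cholesterol synthesis genes rose in 12 of 15 (13 adjusted over the list alone), with Cyp51 at 2.86 and Sqle at 2.75, at 8.4e-08 and at 0.046 with the estimated correlation. FOXO targets fell in 10 of 13, led by the transcription factor Klf2 (-3.96), Rag2 (-3.2), Rag1 (-2.88) and the chemokine receptor Ccr7 (-2.43), at 2.3e-07 and at 0.046 with the estimated correlation. NF-kB targets fell in 10 of 14 and rose in 1, with Cd40 at -4.11 and Bcl3 at -3.31, at 0.0004 (adjusted p = 0.36 with an estimated correlation). DNA replication genes rose in 11 of 23 (15 up and 1 down adjusted over the list alone), with Tk1 at 1.63, at 2.5e-05 (adjusted p = 0.26 with an estimated correlation), and mitosis genes in 10 of 21 with 2 that fell (11 and 3 adjusted over the list alone), with Cdk1 at 1.44, at 0.016 (adjusted p = 0.41 with an estimated correlation).

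ATF4 targets rose in 8 of 11, with Chac1 at 2.59 and Asns at 1.84, at 0.0026 (adjusted p = 0.41 with an estimated correlation). Members of the glycolysis list rose in 6 of 14 (6 up and 1 down adjusted over the list alone), or 6 of 13 without Pigq (adjusted p = 0.0033, and adjusted p = 0.42 with an estimated correlation), with Ldha at 2.05 and Hk1 at 1.49, and the full list passed at 0.0028 (adjusted p = 0.43 with an estimated correlation). Immediate early genes fell in 7 of 16 and rose in 1, with Fos at -2.11 and Btg2 at -2.63, whereas the nuclear receptor Nr4a1 rose by 2.27. This list passed at 0.029 (adjusted p = 0.46 with an estimated correlation) but not without pro-B replicate 1 (0.065) or 2 (0.068) or with the stricter filter (0.1; range over settings 0.0042 to 0.46). Homologous recombination genes rose in 3 of 12, with the nuclease Exo1 at 1.39, at 0.035 (adjusted p = 0.18 with an estimated correlation), a call lost without pre-B replicate 3 (0.083), pro-B replicate 1 (0.056) or pro-B replicate 2 (0.06) and with the stricter filter (0.071; range over settings 0.00061 to 0.18). For called lists without such a count, in this and the other comparisons, the numbers adjusted over the list alone were the same.

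All 19 myeloid markers fell from pre-B to pro-B cells, at 8.7e-12 (adjusted p = 0.16 with an estimated correlation), with S100a9 at -6.04, S100a8 at -4.92 and Mpo at -4.57. Camp (-8.26), Lcn2 (-6.14) and Hp (-5.58) fell with them, and the S100a8 probe set can read related transcripts. H2-Ea fell by 6.32 and Iglv1 by 6.02. The cytoplasmic Fc receptor-like gene Fcrla fell by 5.59, and the highest other genes in pro-B cells were Myl10 (7.97), Efhd1 (6.54), the glycine decarboxylase Gldc (6.24), Tgfb3 (5.96), Foxc1 (5.34), Ift43 (5.28) and the myosin Myh10 (5.28). Bcl6 fell by 1.53 (adjusted p = 0.0014) and Il7r by 1.37 (adjusted p = 0.0011). Btk passed at -0.52 (adjusted p = 0.048), but not when any 1 of 7 arrays was left out (0.056 to 0.14), with the replicate block (0.1), median centring (0.34), hybridization controls (0.34), no filter (0.078) or no offset (0.05; range over all settings 0.0065 to 0.34). Cd79a (-0.08, 0.79), Cd79b (-0.66, 0.074), Blnk (0.49, 0.11) and Prkdc (-0.51, 0.18) did not pass. Cd79b passed without leukaemia replicate 3 (0.03), without pro-B replicate 3 (0.046), with quantile normalization (0.016), with array weights (0.0034) and with a variance trend (0.039), the range being 0.0034 to 0.25. Blnk passed only with array weights (0.05 after rounding), its adjusted p ranging from there to 0.25. The 15 lists not called had adjusted p from 0.082 to 0.86. Without pre-B replicate 2, 2464 genes changed, and with each array's median as the standard the split was 2514 higher and 1236 lower with a median shift of 0.17, or 2168 and 1071 with hybridization controls.

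**Figure D3:**
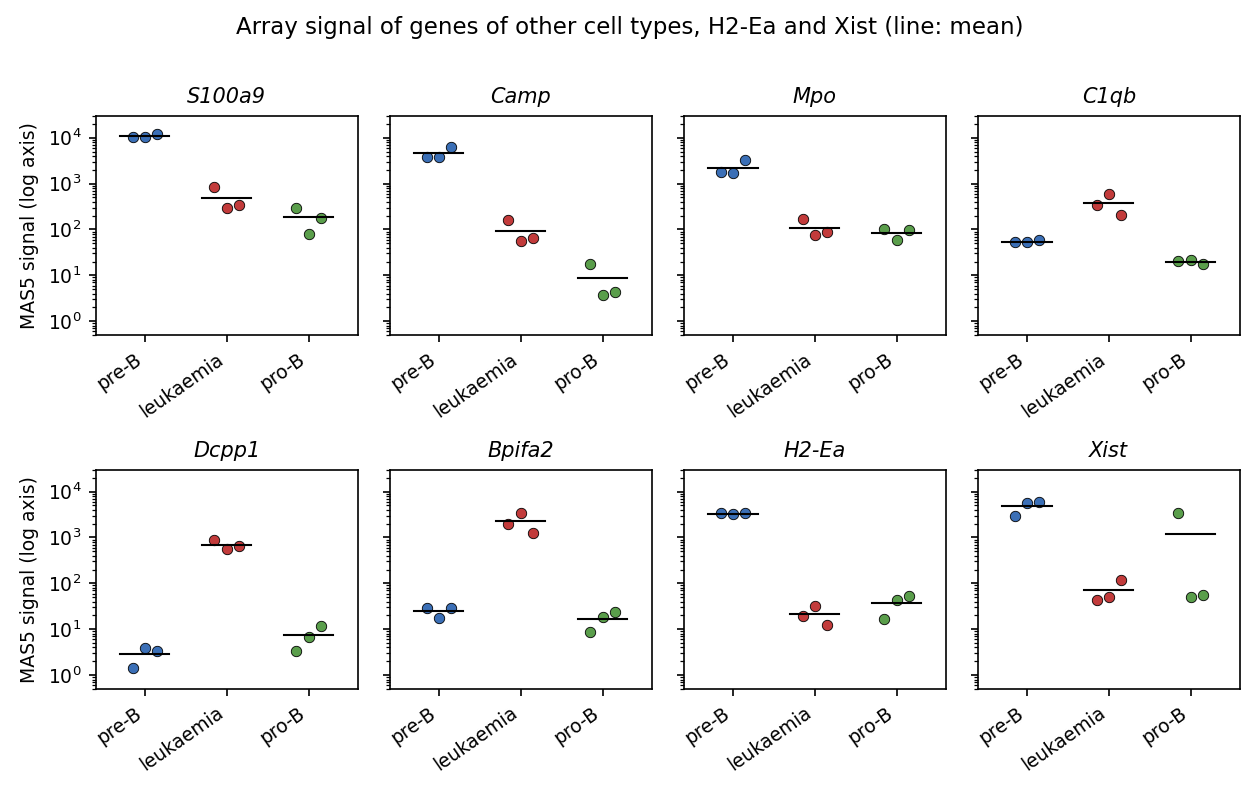
MAS5 signal on a log axis (vertical) of granulocyte and macrophage genes, salivary genes, H2-Ea and Xist in the 3 groups (horizontal). Each point is an array and each line the mean of 3 arrays. H2-Ea signals were 3350, 3210 and 3360 in the pre-B arrays and at most 52 elsewhere, and Xist differed between pro-B arrays (3450, 49.9 and 54.9).

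The spread between replicates and the RNA quality differed somewhat between groups. The median SD of a gene on the log2 scale was 0.195 in pre-B cells, 0.297 in leukaemias and 0.276 in pro-B cells. The ratio of 3' to 5' actin signal was 1.18 ± 0.0298 in pre-B cells, 1.14 ± 0.0239 in leukaemias and 1.1 ± 0.0332 in pro-B cells (n = 3). That of Gapdh was 0.957 ± 0.213, 0.765 ± 0.0414 and 0.768 ± 0.0209, with pre-B arrays at 1.12, 1.03 and 0.716. Hybridization controls had mean signals of 1920 ± 114, 2500 ± 152 and 1730 ± 384.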

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

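Scaling to hybridization controls and the lists without Pigq or Myc were chosen after the data were seen, and all other alternatives were planned. The counts of changed genes were 4092 for leukaemia against pre-B cells, 3153 against pro-B cells, 3818 for pro-B against pre-B cells and 1576 shared by both leukaemia comparisons. Leaving out each array in turn gave 2991 to 4740, 2434 to 3224, 2464 to 3885 and 1194 to 1808, the lowest for pro-B against pre-B without pre-B replicate 2. These fits used the genes tested with all 9 arrays. Requiring at least 2-fold gave 2476, 1888, 2260 and 802, because fewer genes meet both conditions. Testing all probe sets gave 7895, 5266, 7486 and 2492, because 26623 probe sets were tested. The other alternatives stayed within 1.5 times of these counts. With the replicate number as a block the counts were 3561, 2612, 3199 and 1271. The numbers do not pair the samples: deviations of same-numbered arrays correlated at -0.35 to 0.16, with 2 of 9 over 0.1, and not every sample correlated best with its own number. The median SD moved by more than its spread with the larger offset (0.173 in pre-B cells, 0.26 in leukaemias), median centring (0.22 in pre-B cells), no filter (0.23 and 0.328) and the stricter filter (0.17 and 0.272), and the cause was not tested.

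Of 325 named calls, 268 kept direction and call in every setting in which they were tested, up to 21, 54 lost the call in at least 1, and 3, all of Igll1, reversed. Without probe sets that can read related transcripts, Igll1 changed by 1.3 against pro-B cells, 0.11 against pre-B cells and -1.18 between the normal groups, because another probe set is read. Differences that had not passed also changed sign: Cd79b in leukaemia against pro-B cells to -0.12 with quantile normalization and -0.36 with hybridization controls, Btk there to -0.17 with hybridization controls, and Cd79a in pro-B against pre-B cells to 0.15 with median centring and 0.09 with hybridization controls. Syk in leukaemia against pro-B cells became 0.28, and Bcl6 0.03, with the mean of probe sets, because other probe sets of these genes stood higher than the ones used. Syk became 0.02 and 0.09 without leukaemia replicates 1 and 3 and -0.29 without replicate 2, which had the highest Syk signal of the leukaemias (3380 against 2200 and 2000). The cause of the other sign changes was not tested. Of 33 list calls, 33 held with quantile normalization, without the filter and with a variance trend, 32 with the replicate block and with fry, 26 with the stricter filter and 3 with an estimated correlation. For every called list except the erythroid markers, the estimated correlation gave the highest adjusted p of all settings. Signal over background limits the dim genes, for which no detection calls were used.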

Other observations

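Tests of the number of salivary genes, of the block beside Igh and of H2-Ea were chosen after the result was seen, whereas those of the salivary and epithelial medians, of the neighbours of Myc and of other splits were written before. The genes of the next paragraph were chosen after their values were seen.

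Ccnd1, a D-type cyclin that is usually low in normal B cells, had a signal of 1630 ± 427 in leukaemias, 218 ± 41.6 in pre-B cells and 40.5 ± 16.3 in pro-B cells (n = 3), while Ccnd3 fell from 2880 ± 268 in pre-B cells to 870 ± 168. Between leukaemias 292 genes had an SD over 1 on the log2 scale, against 109 in pre-B and 288 in pro-B cells. The potassium channel Kcnk1 had signals of 2.11, 153 and 1060 in leukaemia replicates 1, 2 and 3, the cytotoxic protease Gzma 643, 66.9 and 59.7, and the Y-linked Eif2s3y 144, 7.08 and 0.816. Eif2s3y gave 122, 93.5 and 70.1 in the pre-B arrays, which also had high Xist. The median gene of chromosome 3 stood at 0.37, 0.1 and 0.17 above the normal groups in the 3 leukaemias, the highest of all chromosomes in each. The next highest were chromosome 13 (0.17) in leukaemia 1 and chromosome 15 in leukaemias 2 (0.06) and 3 (0.11). In leukaemia 1 the medians of most chromosomes were positive. No cause was tested.

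Salivary secretory genes were among the strongest to rise in every leukaemia array, which a few salivary gland cells taken with the node may explain. Of 15 other measured salivary genes, 5 (Amy1, Car6, Dcpp3, Pip and Cst10) were higher than in both normal groups in a fit without the low-signal filter, against a median of 0 and a highest of 4 in 10000 random lists of matched signal, although Amy1 and Cst10 lay below the filter. The Dcpp3 probe set can read related transcripts, and Dcpp1 was among the genes that prompted the test, so Dcpp3 may not count separately. The median of 0.77 over the 15 salivary genes (95% interval 0.21 to 2.24) left salivary gland cells open, as only 8 lay above the filter. The median of epithelial genes, 0.3 (0.04 to 0.53), lay under the bound that the rule written before set against epithelial tissue. By that rule, which used the median alone, the test argued against such tissue. The upper end of the interval passed the bound, and only 8 of 15 epithelial genes lay above the filter. A small amount of epithelium was therefore not excluded. Both intervals came from resampling the genes of a list and do not measure the spread between arrays. Signals in the 3 leukaemias were 2010, 3400 and 1280 for Bpifa2, 899, 549 and 655 for Dcpp1, 160, 681 and 2960 for Scgb1b27 and 274, 386 and 2370 for Car6, which do not rank as levels across probe sets. Leukaemia samples held at least 85% CD19-positive cells by flow cytometry, which leaves room for some other cells. The labels name a sort, but the sorted pre-B arrays still had high signals of granulocyte genes such as S100a9 (mean 11100). A sort therefore does not exclude RNA of other cells here. Expression by the leukaemia cells themselves was not tested.

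Neighbours of Myc and of the Igh constant genes were raised in some leukaemias, for which a candidate explanation is a gain or rearrangement joining these regions, a hypothesis that was not tested, as no DNA was measured. The 10 tested genes nearest Myc, 5 on each side, had a median of 0.32, at percentile 91.2 of all such windows. This neither excludes nor bears out a regional gain, since a window over both sides can miss a gain on 1 side. In the 3 leukaemias Pvt1 stood at 4.51, 0.93 and 4.64, Trib1 at 2.81, 6.09 and 4.07 and Nsmce2 at 1.54, 2.02 and 2.7. All tested genes from Fbxo32 to Lratd2, on the Trib1 side of Myc, had positive means, from 0.19 to 4.32. On the other side Gsdmcl2 (-1) and Cyrib (-0.3) had negative means, and those of Gm20740 (0.13) and Asap1 (0.03) were small. The run of positive means was seen only afterwards and was not tested. Beside Igh on chromosome 12, 15 neighbouring genes from Siva1 to Crip2, Akt1 among them, had a median of 1.46, above the highest of 1000 shuffled orders (1.28), which argues against chance order. Their medians were 2.7, 2.16 and 0.1 in leukaemias 1, 2 and 3, so the block was not raised in the last, although Myc stood at 5.16, 5.19 and 5.25. Regulation of neighbouring genes together stays open, since the widest such shift between the normal groups was -1.19.

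H2-Ea was high in the sorted pre-B arrays and near the filter level elsewhere. Lower class II expression in the leukaemias is argued against by a mean change of 0.91 (SD 0.32) of H2-Aa, H2-Ab1, H2-Eb1 and Cd74, and a fault of a probe set by -5.06 at another H2-Ea probe set. Mice of the C57B/6 type carry an H2-Ea gene that is not expressed, so RNA of another strain in samples labelled C57B/6 is a candidate explanation. The lowest pre-B signal of 3210 is the pattern itself and gives no separate evidence for it. The explanation remains a hypothesis, since no other strain marker was tested.

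Other splits of the arrays were refitted. For each of the 3 comparisons, 10 splits of 3 against 3 are too few for a share under 0.05, with only 1 split, the real one, as large: 4092, 3153 and 3818 genes, and 0 at the highest of the others. For the overlap, 1 of 100 drawn splits, the real one, gave as many as 1576 genes and the highest other gave 1178. This excludes only a random labelling of the arrays and is no test of the overlap itself, because every other drawn split mixed groups that differ. The 1 other split that kept the leukaemia arrays together gave 559.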
